A study of Atriplex prostrata and Atriplex rosea and Atriplex prostrata x Atriplex rosea with 33 samples.

How the data were processed

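Messenger RNA of 2 saltbush species was measured by RNA sequencing: Atriplex prostrata, which fixes carbon by the C3 pathway, and Atriplex rosea, which uses the C4 pathway. Per the labels' protocols, plants were grown in chambers at 27 °C by day and 22 °C by night with 17 h of light of about 500 µmol per square metre and second. The middle of mature leaves of a primary branch or of the main stem, stem and root were frozen. Harvest was 2 h after the onset of light for all samples. Total RNA was made into libraries with a TruSeq RNA kit, 12 libraries to a lane, and sequenced on a HiSeq in single-end or paired-end mode. Which library had which mode is not given in the sources used here, and neither is the aligner or any use of strand. The submitters' processing notes name the Arabidopsis thaliana genome build TAIR10 and the tools CASAVA and DESeq2, with no versions. Values stand beside Arabidopsis locus codes, so a value is the signal of reads assigned to an Arabidopsis locus. Reads of near-identical gene copies may have been assigned to either copy, and members of gene families are uncertain for that reason. Whether reads of the 2 species were assigned to a locus equally well was not tested.

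The authors' deposited table holds whole read counts per locus for 18 libraries of 6 groups, which the authors did not normalize, per the file headers. It holds RPM, reads scaled to a library total, for 21 libraries of 7 groups, which the authors scaled to each library's total and rounded to whole numbers, per the file headers. The RPM values are used here as score values, which the authors scaled to each library's total and rounded before deposit, per the file headers. It also holds the authors' own log2 fold changes and q-values for C4 against C3 in each organ, per the file headers. The sign of the deposited log2 values was found from their correlation with the RPM, which was 0.993 to 0.995 after turning them to C4 minus C3 in both leaf positions and stem. The root values were assumed to have the same sign. Of 21976 lines in the table, 5 were left out because extra tabs shift their values. The columns taken as main-stem leaves carry a prefix read as stem in their names. Of 33 samples in the labels, 12 are not analysed here: 9 leaf samples of hybrids and 3 samples of C3 root. Comparisons that need them were left out, so root was compared between species only through the authors' deposited table. The smallest chi-square per degree of freedom between 2 libraries of a group was 2.52, so no 2 of the libraries with counts that were compared differed by as little as sampling noise.

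Library totals ranged from 3583928 to 20791409 counts. The C3 stem has RPM only, so its depth and its share of even counts are unknown. In the 12 leaf libraries 69.0% to 72.9% of the counts from 1 to 20 were even, against 45.1% to 46.4% in the 6 libraries of C4 stem and root, which is how counts look where both reads of a pair are counted. Leaf totals may therefore count a fragment more than once, and counting precision in leaf would then be below what the totals give. The RPM value equalled the rounded share of the counts in 92.9% to 98.3% of loci per library.

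Counts were tested with edgeR 4.0.16 in R 4.3.3: loci kept by filterByExpr, TMM scaling, quasi-likelihood test, Benjamini-Hochberg adjustment at 0.05, 1 mean per group and no covariate. The leaf comparisons used the 12 leaf libraries, with a species' leaf level as the mean of its 2 leaf positions. C4 root and stem against C4 leaf used all 18 libraries. The planned count test could not be used where C3 stem enters, so these comparisons used limma 3.58.1 with a trend on log2(RPM + 1) over 21 libraries, at loci with an RPM of at least 5 in at least 3 libraries. Fold changes on this scale understate the change of low loci. RPM is scaled to library totals only, and the 10 most abundant loci took 18.7% to 23.9% of the reads of C3 leaf libraries against 6.97% to 8.01% in C3 stem. RPM of all other loci is lowered in leaf as a result, and a second scaling by median ratios (RLE) is given beside these results.

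The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 19 lists hold 308 genes, of which 243 have a line in the table. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule names the highest-expressed member of each family of PPC, PPDK, NAD-ME, NADP-ME, ASP, ALAAT and BCA, up to 4 members of each list with the smallest adjusted p, and the 6 highest and 6 lowest fold changes among loci called, separated in every library and at 20 CPM or more. Gene names come from the fixed lists or from the descriptions in the table. Values are means ± SD over libraries in CPM (counts scaled to the library total) of the fit they belong to, or in RPM where limma was used. Where a group had 0 counts, a bound was computed against 3 counts over the whole group. Such bounds cover counting error only, and are up to 2-fold too high where leaf counts hold both reads of a pair.

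Alternatives were RLE scaling, no filter, DESeq2 1.42.0 on the counts, other pseudocounts, only the groups compared, a replicate block, each leaf position alone, leaf libraries summed, a 2-fold threshold and leaving out each library in turn. Chosen after seeing the data were limma on RPM in place of edgeR, thinning to equal totals, leaving out libraries in doubt, halving of the leaf counts and RLE scaling for the overlap and the lists. The tests were tried on simulated data with 200 changed loci per comparison. At 4-fold changes 77% of 100 loci were recovered in the leaf comparison of species, run on 12176 loci, and at 2-fold changes 32%. For leaf position these were 48% and 3% in C3 and 55% and 6% in C4, and for the leaf minus stem difference 57% and 5%. No simulated locus was called in the wrong direction. The simulation assumed equal composition of the libraries and says nothing about the RPM scale. It gave C3 stem libraries the depth of C4 stem libraries, since their own is unknown. It took 1 spread per locus for all libraries, although leaf libraries lay further from their groups than C4 stem and root libraries.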

Results

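Transcript levels were compared between leaf, stem and root of Atriplex prostrata (C3) and Atriplex rosea (C4), 2 saltbush species of 1 genus that differ in how they fix carbon. In C4 plants phosphoenolpyruvate carboxylase first binds carbon, taken as bicarbonate, and the acid made is broken down again in an inner cell layer around Rubisco. There were 3 libraries each of branch leaves and main-stem leaves of both species, C3 stem, C4 stem and C4 root. Totals ranged from 3583928 counts in a C4 branch leaf library to 20791409 in a C3 branch leaf library. The labels name replicates but not the plants they came from, so p-values may measure only the spread between samples, which may be technical. The first principal component of the 18 libraries with counts held 56.3% of the variance and the second 14.5%. Leaf libraries lay further from the rest of their group (root mean square log2 distance of 0.66 to 1.21) than C4 stem and root libraries did (0.24 to 0.31).

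The first question was which genes differ between C4 and C3 leaves. PPDK (AT4G15530), which regenerates the carbon acceptor, stood at 25290 ± 11800 CPM (SD, n = 6) in C4 leaves and 703 ± 126 in C3 leaves, a log2 fold change of 5.18 ± 0.45 (SE) with an adjusted p of 4.95e-06. PPC1 (AT1G53310), a phosphoenolpyruvate carboxylase, was higher in C4 leaves (11160 ± 5820 against 1776 ± 608 CPM, log2 2.66). NAD-ME1 (AT2G13560), a mitochondrial decarboxylase, was at 2503 ± 773 against 112 ± 8.54 CPM (log2 4.48). The alanine aminotransferase ALAAT1 (AT1G17290) reached 9518 ± 6630 against 93.6 ± 14.8 CPM (log2 6.67). The aspartate aminotransferases ASP1, ASP2, ASP3 and ASP4 were higher by 5.07, 5.65, 5.08 and 5.41. C4 main-stem leaf replicate 1 had the lowest RPM of the C4 leaf libraries for PPC1 (2551 against 10246 to 19675), PPDK (10005 against 20248 to 35779), NAD-ME1 (1538 against 2479 to 3252), ALAAT1 (641 against 6397 to 17160) and ASP1 (381 against 1855 to 3637). The carbonic anhydrase BCA1 (log2 0.24, adjusted p = 0.702) and NADP-ME2 (log2 -0.19, adjusted p = 0.495) did not pass the edgeR test. Of 26 measured C4 cycle enzymes 14 rose in C4 leaves, 2 fell (BCA3, log2 -1.36, and ASP5, log2 -1.65, both chosen after their values were seen) and 10 did not pass, with the same counts adjusted over the list alone. Camera gave the list an adjusted p of 8.01e-05, and adjusted p = 0.887 with an estimated correlation. Of 11 measured transporters 6 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 3.49. They included the pyruvate carrier BASS2 (5739 ± 2510 against 104 ± 38.4 CPM, log2 5.79) and the mitochondrial dicarboxylate carriers DIC1 (5.79), DIC3 (4.30) and DIC2 (4.81). The list had an adjusted p of 5.49e-04 by camera, and adjusted p = 0.887 with an estimated correlation.

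**Figure D1:**
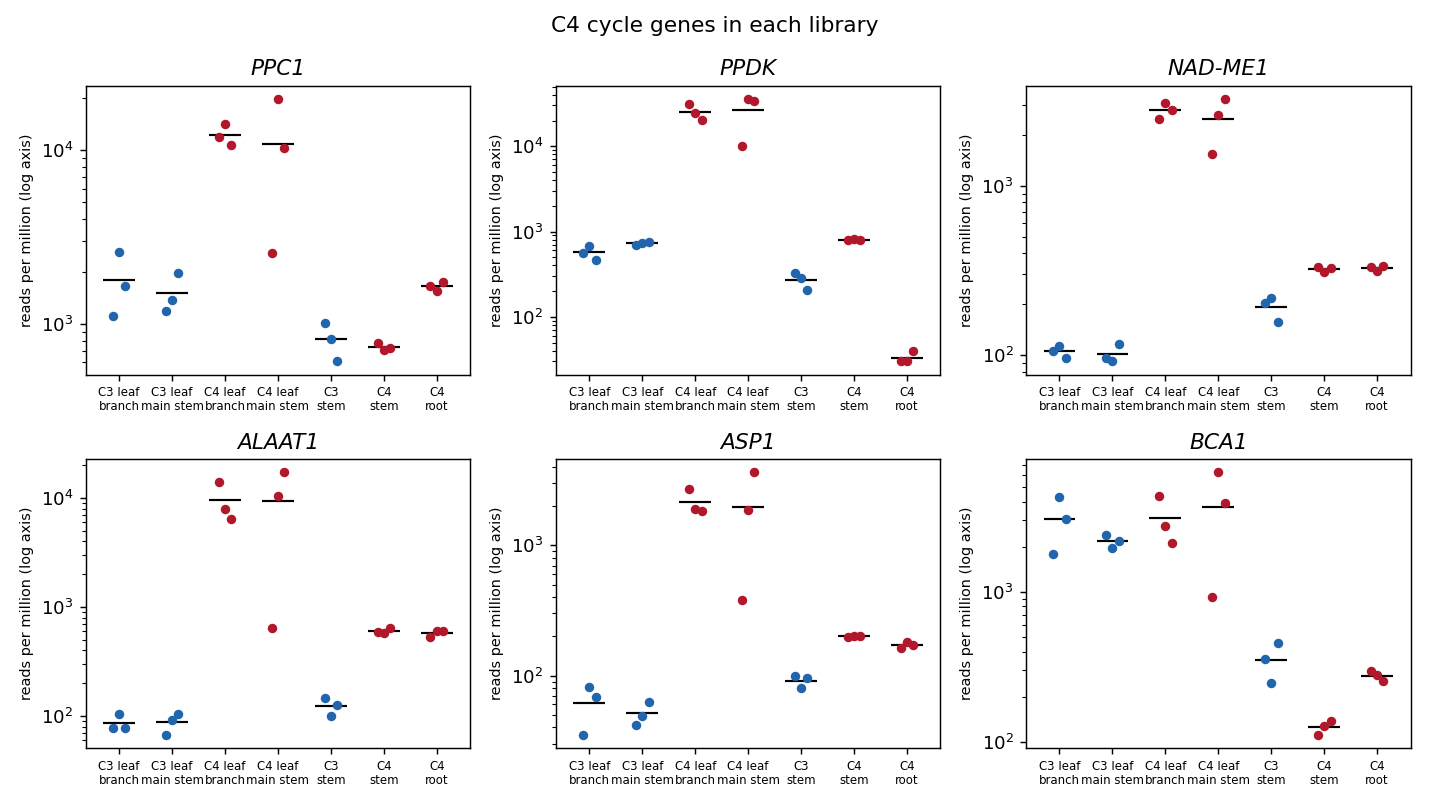
RPM on a log axis of 6 C4 cycle genes in each library, with points for the 3 libraries of a group and a bar for their mean, C3 in blue and C4 in red. PPDK lies between 10005 and 35779 in C4 leaf libraries and between 460 and 761 in C3 leaf libraries, while BCA1 overlaps between the species in leaf, and PPC1 does at 2551 in 1 C4 leaf library against 2589 in 1 C3 leaf library.

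Of 21 measured genes of photorespiration, the salvage of the product of Rubisco's reaction with oxygen, 11 fell in C4 leaves, 1 rose and 9 did not pass, and adjusted over the list alone 15 fell and 1 rose. GLYK fell from 224 ± 23.1 to 64.8 ± 23.8 CPM, the plastid glycolate exporter PLGG1 from 941 ± 243 to 88.6 ± 52.5, GOX2 from 1302 ± 174 to 255 ± 99.1 and HPR1 from 2626 ± 385 to 862 ± 195. GLDH2, a subunit of glycine decarboxylase named after its value was seen, rose by a log2 fold change of 3.04. The list had a median of -1.17 and an adjusted p of 1.02e-04 by camera, and adjusted p = 0.887 with an estimated correlation. In the Calvin-Benson cycle 6 of 17 genes fell and 2 rose, over all loci and over the list alone. RPI3 (-2.14), FBA3 (-2.17), the Rubisco activase RCA (-2.33) and the Rubisco small subunit RBCS1A (-3.34) fell, and the regulators CP12-1 (1.36) and CP12-2 (0.86), chosen after their values were seen, rose. The adjusted p was 0.00325 by camera, and adjusted p = 0.887 with an estimated correlation. Of 14 photosystem II genes 7 fell and 0 rose, or 11 and 1 adjusted over the list alone, among them PSBQ2 (-1.44), and the list had an adjusted p of 0.00325, and adjusted p = 0.887 with an estimated correlation. With main-stem leaves only PSBQ2 (-1) and CP12-2 (0.79) were not called. Of 12 photosystem I genes 2 fell, PSAE2 and LHCA1, and 0 genes did so adjusted over the list alone. Neither passed with 1 leaf position alone. PSAE2 was not called without C3 branch leaf replicate 1 (-0.77) or C3 main-stem leaf replicates 1 and 2 (-0.78 and -0.82), and LHCA1 was not called without any other library (-0.90 to -0.74) than C3 main-stem leaf replicate 3 or C4 main-stem leaf replicates 1 and 3.

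Among the other lists, 6 of 19 genes of cyclic electron flow rose and 0 fell, among them NDHO (170 ± 61.9 against 55.4 ± 7.45 CPM), and the list itself did not pass camera (adjusted p = 0.216). The starch breakdown genes MEX1 (-2.56) and DPE2 (-2.47) fell while SUS4, a sucrose synthase, rose (1.57), so that 4 genes of starch and sucrose fell and 1 of 20 rose. The chlorophyll synthesis genes PORB (-1.37) and PORC (-1.31) fell, with 1 of 10 rising. Of 10 regulators of leaf patterning 2 rose and 2 fell, among them ATHB8 (1.91), known from procambium, and the plastid regulator GLK2 (-1.48). Of 20 secondary wall and lignin genes 5 rose, among them F5H1 (3.53) and COMT1 (1.31), and 1 fell. The senescence genes NAP (3.73) and SAG12 (3.75) were the 2 of 5 that rose. SLAC1 was the 1 of 4 epidermis and guard cell genes that fell (-1.70). In heat and salt stress 1 of 11 rose, APX2 (1.33), and 3 fell, among them P5CS1 (-0.98). Of 3 genes of cell division 1 rose, PCNA1 (1.61), and 1 fell, MCM5 (-1.98), which was called only without C4 branch leaf replicate 1 (-2.69) or C4 main-stem leaf replicate 3 (-3.25) and with no library left out. Of 10 clock genes 2 rose and 1 fell. The risers GI and CCA1 lost their calls without 1 library in 8 and 9 of 12 cases (0.46 to 0.78 for GI and 0.42 to 0.56 for CCA1). With main-stem leaves only PORB (-1), PORC (-0.92), GLK2 (-1.33), SAG12 (2.32), APX2 (0.90) and P5CS1 (-0.57) were not called. None of 4 root markers, 3 phloem genes and 2 defence genes was called by edgeR. None of these lists passed camera, with adjusted p of 0.15 or more, and defence had too few genes for it. The leaf patterning list has a median of -0.04 beside an upward test, and senescence a median of 0.17 beside a mean of 1.46.

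Among the highest fold changes, AT3G16150 (described as an aminohydrolase) had 26.5 ± 9.11 CPM in C4 leaves and 0 counts in C3 leaves, at least 696-fold higher against 3 counts over the group. This bound is up to 2-fold too high if leaf counts hold both reads of a pair. It also holds only if reads of both species are assigned to this Arabidopsis locus equally well, which was not tested. ICL, isocitrate lyase of the glyoxylate cycle, was at 1515 ± 2150 CPM against 0.984 ± 1.08, and its level differed between C4 leaf libraries from 161 to 7700 RPM. Without C4 main-stem leaf replicate 1, which had the 7700, the log2 fold change of ICL was 9.4 instead of 10.85. Among the lowest fold changes were MT3, a metallothionein (0.127 ± 0.203 against 265 ± 111 CPM), and AT5G17630 (0.249 ± 0.465 against 50.8 ± 18.4 CPM). The log2 fold change of MT3 was -10.55, and -12.42 without C4 branch leaf replicate 3 and -12.45 without C4 main-stem leaf replicate 1, and that of AT5G17630 was -7.72, and -10.35 without C4 branch leaf replicate 1. In all, edgeR called 4320 of 12416 loci after Benjamini-Hochberg adjustment, 2150 higher and 2170 lower in C4 leaves. At least a 2-fold difference was found for 2803 of them, and branch leaves alone gave 2337 loci and main-stem leaves alone 2232. Limma on the RPM values called 3651, of which 64.7% were higher against 49.8% with edgeR.

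Leaf position was compared within each species. None of the named C4 cycle, photorespiration or photosystem genes passed the test between main-stem and branch leaves in either species. EdgeR called 0 of 12416 loci in C3, with 345 at an unadjusted p under 0.05, and 0 in C4, with 458. DESeq2 called 3 in C3 and 1 in C4. Of simulated 2-fold changes 3% and 6% were recovered here in C3 and C4, and of 4-fold changes 48% and 55%. By camera the secondary wall list, with 0 of 20 genes called in either species, was lower in main-stem leaves of C3 (median -0.30, adjusted p = 0.00179) and of C4 (median -0.29, adjusted p = 0.00667), with adjusted p = 0.692 and adjusted p = 0.979 with an estimated correlation. C4 main-stem leaf replicate 1, 1 of the 3 C4 main-stem libraries, lies apart on this list, with a mean log2 CPM of 4.11 against a median of 5.09 in the other C4 leaf libraries. The senescence list passed camera upward in C3 main-stem leaves with 0 of 5 genes called (median 0.74, adjusted p = 0.0472, and adjusted p = 0.692 with an estimated correlation).

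C4 root was compared with C4 leaf to ask where the C4 genes are expressed. PPDK was at 18.9 ± 3.23 CPM (n = 3) in root and 33440 ± 15700 (n = 6) in leaf, on the scale of the fit with stem and root, and fell by 10.79 on the log2 scale with an adjusted p of 3.97e-10. PPC1 (-3.98), NAD-ME1 (-4.15), ASP1 (-4.78), ALAAT1 (-5.25) and BCA1 (-4.81) also fell. NADP-ME2 was higher in root (155 ± 10.8 against 114 ± 31.8 CPM, log2 0.47, adjusted p = 0.0429). It was not called with branch leaves only (0.21) or without C4 branch leaf replicates 1 and 3 (0.44 and 0.40), C4 main-stem leaf replicates 2 and 3 (0.44 and 0.46) or C4 root replicate 1 (0.53). Of 26 C4 cycle enzymes 17 fell and 5 rose, over all loci and over the list alone, and the risers chosen after their values were seen included the carboxykinases PCK1 (4.06, or 4.91 without C4 branch leaf replicate 1) and PCK2 (4.74, or 5.88 without C4 main-stem leaf replicate 1). The adjusted p was 4.06e-05 by camera, and adjusted p = 0.191 with an estimated correlation. All 14 measured photosystem II genes, 12 photosystem I genes, 19 cyclic electron flow genes and 10 chlorophyll synthesis genes fell, such as PSBO2 (7990 ± 1580 CPM in leaf, 5.16 ± 0.0772 in root). So did 16 of 17 Calvin-Benson genes, among them CP12-1 (-11.02), 19 of 21 photorespiration genes, among them HPR1 (-6.32), and 10 of 11 transporters, among them BASS2 (-7.08). Their adjusted p by camera lay at 3.21e-05 or below, and with an estimated correlation none passed (adjusted p = 0.0751 for photosystem II and adjusted p = 0.189 for the transporters). Of 12 root markers 10 rose and 0 fell, among them the nitrate transporter NRT2.1 (47.2 ± 7.75 against 0.121 ± 0.145 CPM), MYB36 (6.22) and CASP5 of the Casparian strip, which had 0 counts in leaf and was at least 580-fold higher against 3 counts over the group. That bound is up to 2-fold too high if leaf counts hold both reads of a pair. The root marker list had an adjusted p of 2.78e-05, and adjusted p = 0.04995 with an estimated correlation. All 6 cell division genes rose, among them CYCB1;1 (5.05, adjusted p of the list 0.013), as did 16 of 23 secondary wall genes, among them FLA12 (4.67), with an adjusted p of 0.00391, and adjusted p = 0.16 and 0.237 with an estimated correlation. Lower in root by camera were also starch and sucrose (16 fell, 3 rose, adjusted p of 3.21e-05), phloem (3 of 3 fell, 0.00696), epidermis (4 of 4 fell, 0.00703) and clock genes (5 fell, 1 rose, 0.0156), with adjusted p = 0.16, 0.0751, 0.18 and 0.16 with an estimated correlation. Without C4 branch leaf replicate 3 the log2 fold change of NRT2.1 was 10.06 instead of 8.44, and without C4 branch leaf replicate 1 that of FLA12 was 5.32. The clock genes LHY (-3.56) and CCA1 (-3.45) fell. EdgeR called 9386 of 14486 loci, 5388 higher and 3998 lower in root. Directions are against 0, and the median log2 fold change over all loci was 0.235. In the leaf libraries 69.0% to 72.9% of low counts were even against 45.1% to 46.4% in root and stem. In a test against a 2-fold change, the most that counting both reads of a pair can do, 5601 loci passed in root and 4644 in stem, and differences within 2-fold cannot be told from counting. If leaf was sequenced in another mode than root and stem, other effects of the mode cannot be told from organ at any fold change.

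C4 stem was compared with C4 leaf in the same fit. PPDK was at 468 ± 7.66 CPM (n = 3) in stem and fell by 6.15 on the log2 scale with an edgeR adjusted p of 7.57e-08, and PPC1 (-5.10), NAD-ME1 (-4.13), ASP1 (-4.52), ALAAT1 (-5.15) and BCA1 (-5.91) fell as well. NADP-ME2 was higher in stem (196 ± 15.9 CPM, log2 0.81, adjusted p = 0.00157), and not with branch leaves only (0.55, adjusted p = 0.0531). Of 26 C4 cycle enzymes 18 fell and 3 rose, with the same counts over the list alone and an adjusted p of 5.55e-06, and adjusted p = 0.234 with an estimated correlation. All 14 photosystem II, 12 photosystem I, 19 cyclic electron flow and 10 chlorophyll genes fell, by less than in root: the medians were -2.63, -3.13, -3.93 and -2.26 in stem and -9.85, -10.54, -10.17 and -6.92 in root, a difference that was not tested. Photorespiration (19 of 21 fell), the Calvin-Benson cycle (14 of 17) and the transporters (7 of 11, or 8 adjusted over the list alone) were lower too. These 7 lists had adjusted p of 2.35e-04 or below by camera, and adjusted p = 0.177 to adjusted p = 0.253 with an estimated correlation. Starch and sucrose (13 fell, 4 rose, 0.00482), phloem (3 of 3 fell, 0.00749) and senescence genes (3 fell, 1 rose, 0.0148) passed camera downward as well, with adjusted p = 0.304, 0.177 and 0.253 with an estimated correlation. Of 23 secondary wall genes 17 rose, among them CESA8 (199 ± 17.8 against 67.8 ± 10.1 CPM) and FLA11 (47.4 ± 7.27 against 2.32 ± 1.07 CPM), and 1 fell, with an adjusted p of 0.00325, and adjusted p = 0.253 with an estimated correlation. All 6 cell division genes rose, among them CYCA1;1 (7.65, or 10.17 without C4 main-stem leaf replicate 1), with an adjusted p of 0.00736, and adjusted p = 0.177 with an estimated correlation. The shoot meristem gene STM had 81.0 ± 2.16 CPM in stem and 0 counts in leaf, at least 952-fold higher against 3 counts over the group. That bound is up to 2-fold too high if leaf counts hold both reads of a pair. EdgeR called 8793 of 14486 loci, 4878 higher and 3915 lower in stem. Directions are against 0, and the median log2 fold change over all loci was 0.163. Limma on the RPM values called 9231, with 87.1% higher against 55.5% and a median of 1.033, and 321 loci were called in the opposite direction.

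Stem was compared between the species to see whether C4 genes also differ outside the leaf. C3 stem may have been sequenced in another mode than C4 stem, and effects of that could not be told from species. PPC1 stood at 736 ± 35.3 RPM (n = 3) in C4 stem and 813 ± 204 in C3 stem and did not pass the limma test (log2 -0.11, adjusted p = 0.896). PPDK was higher in C4 stem, at 801 ± 11.5 against 272 ± 60.4 RPM (log2 1.58, adjusted p = 0.0027), and PPC4 at 72.0 ± 3.00 against 3.00 ± 1.00 RPM (log2 4.22, adjusted p of 1.73e-07). ALAAT1 (2.29), NAD-ME1 (0.76) and NADP-ME2 (0.74) passed with adjusted p of 0.0241, 0.0152 and 0.0353, and under RLE scaling none of these did, with adjusted p of 0.0802, 0.197 and 0.117. ASP1 did not pass (1.13, adjusted p = 0.106), and did in a fit of the stem libraries alone (limma adjusted p of 5.82e-04). The main fit takes the spread of a locus from all 21 libraries, and leaf libraries lay further from their groups than C4 stem libraries. ASP1 was at 198 to 202 RPM in C4 stem and 80 to 99 in C3 stem. ALAAT1 was at 583 to 641 against 101 to 146, and BCA1 at 111 to 138 against 246 to 459. Without C3 stem replicate 3 or C4 stem replicate 1 NAD-ME1 was at 0.62 and 0.73 and not called. ALAAT1 was not called without C3 stem replicate 2 (2.15), C3 stem replicate 3 (2.3) or C4 stem replicates 1, 2 and 3 (2.31, 2.31 and 2.24), nor was NADP-ME2 without these (0.74, 0.67, 0.71, 0.70 and 0.80). BCA1 was lower (-1.45, adjusted p = 0.0328), and not called without C3 stem replicates 1 and 3 (-1.42 and -1.24) or C4 stem replicates 1, 2 and 3 (-1.37, -1.46 and -1.52). The carriers DIC1 (15 ± 9.54 against 78.7 ± 7.09 RPM), DIC2 (16.3 ± 9.29 against 122 ± 6.81 RPM) and DIC3 (1.67 ± 1.15 against 30.3 ± 4.16 RPM) were lower in C4 stem. Of 26 C4 cycle enzymes 7 rose and 3 fell, or 4 and 3 under RLE scaling, and the list did not pass camera (adjusted p = 0.584). Of 21 secondary wall and lignin genes 19 were lower in C4 stem and 0 higher, or 20 and 0 adjusted over the list alone, and 19 and 0 under RLE scaling. FLA11 (80.7 ± 11 against 564 ± 196 RPM), IRX10 (38.0 ± 2.00 against 143 ± 74.7 RPM), C3H1 (176 ± 6.66 against 497 ± 150 RPM) and COMT1 (231 ± 11.7 against 1210 ± 632 RPM) were among them. With a pseudocount of 0.1 FLA11 (adjusted p = 0.0549) and BCA1 (adjusted p = 0.0512) were not called. The secondary wall list had a median of -1.40 and an adjusted p of 3.04e-14 by camera, and adjusted p = 0.123 with an estimated correlation.

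The photorespiration list passed camera downward in C4 stem with an adjusted p of 0.0416, which was 0.105 under RLE scaling and adjusted p = 0.982 with an estimated correlation; HPR1 was at 90.3 ± 6.66 against 286 ± 28.1 RPM. The nitrate transporter NPF7.3 was higher in C4 stem (171 ± 9.07 against 1.33 ± 0.577 RPM), as was PNSB5 (log2 2.40). The alcohol dehydrogenase ADH1 was lower (91.7 ± 2.08 against 1424 ± 666 RPM), as were BAM5 (-6.03) and AT4G21960 (-5.17), a peroxidase. AT3G16150 (871 ± 94.5 RPM) was listed at 0 in every C3 stem library. Limma called 3425 of 12624 loci, 2369 higher and 1056 lower in C4 stem. Directions are against 0, and the median log2 fold change over all loci was 0.218. Under RLE scaling 3067 were called, 1444 higher and 1623 lower, with a median of -0.003, so the split by direction follows the scaling. The authors' deposited table has 3370 loci higher and 3935 lower in C4 stem at a q under 0.05. Its log2 values of PPDK (1.28), NAD-ME1 (0.50) and PPC1 (-0.37) lie near those under RLE scaling (1.33, 0.51 and -0.36). In that table ALAAT1 (q = 7.94e-05) and BCA1 (q = 2.14e-04) were under a q of 0.05, and NAD-ME1 (q = 0.131) and ASP1 (q = 0.0525) were not. A fit of the stem libraries alone called 5177 loci.

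**Figure D2:**
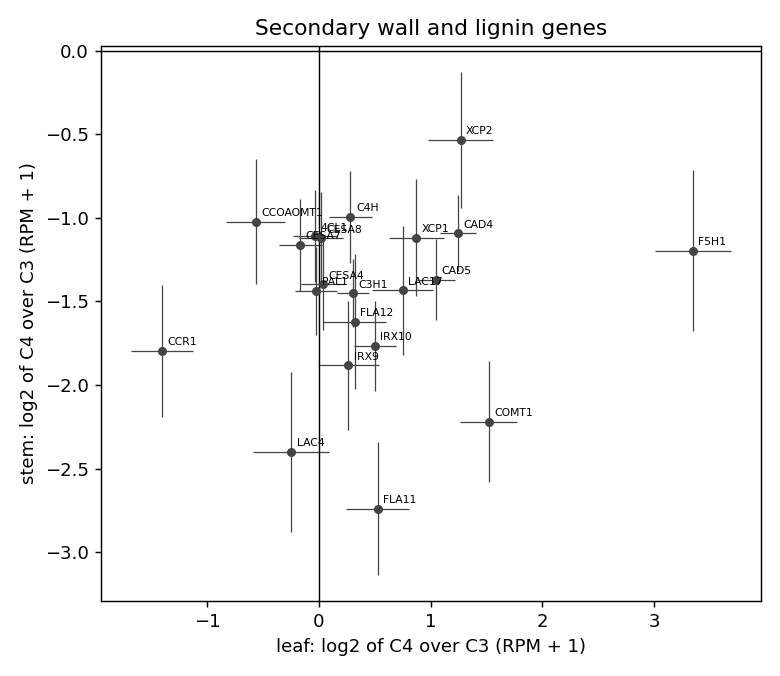
Log2 fold change of C4 over C3 in leaf (horizontal) and in stem (vertical) of the secondary wall and lignin genes, on the log2(RPM + 1) scale, with bars for the standard error. Of 21 tested genes 19 passed the test in stem, all below 0.

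C3 stem was compared with C3 leaf. The sequencing mode of C3 stem is unknown, and if it was not that of leaf, its effects could not be told from organ. Directions are against 0, and the median log2 fold change over all loci was 0.975, or 0.215 under RLE scaling. HPR1 fell from 2441 ± 433 RPM (n = 6) to 286 ± 28.1 (n = 3) and RCA from 46410 ± 6760 to 2474 ± 345 RPM. Their limma adjusted p were 3.82e-12 and 1.29e-11. PPDK was lower in C3 stem (272 ± 60.4 against 652 ± 117 RPM, log2 -1.26, adjusted p = 0.0012, and -2.13 under RLE scaling), as was BCA1 (354 ± 107 against 2621 ± 934 RPM, and -3.74 under RLE scaling). PPC1 was lower too (-0.98, adjusted p = 0.0468, and -1.86 under RLE scaling). Its call was lost with either leaf position alone (-1.08 and -0.89), with no filter and with a pseudocount of 0.1. It was also lost without C3 branch leaf replicates 2 and 3 (-0.83 and -0.99), C3 main-stem leaf replicates 2 and 3 (-1.01 and -0.88) or C3 stem replicates 1, 2 and 3 (-1.16, -1 and -0.79). NADP-ME2 was higher (1.19, adjusted p of 7.50e-05) but not under RLE scaling (0.32), and ASP1 (0.74, adjusted p = 0.136) and ALAAT1 (0.51, adjusted p = 0.473) did not pass. Of 21 photorespiration genes 19 fell, of 17 Calvin-Benson genes 15, of 19 cyclic electron flow genes 17, of 14 photosystem II genes 13, and all 12 photosystem I and 10 chlorophyll genes. Under RLE scaling these were 20, 16, 19, 14, 12 and 10. These lists passed camera also with an estimated correlation, with adjusted p = 0.0228 for photorespiration to adjusted p = 0.0359 for photosystem II. All 21 secondary wall genes rose, under RLE scaling too, among them FLA11 (564 ± 196 against 0.833 ± 0.753 RPM) and CAD4 (269 ± 80.5 against 16.8 ± 2.32 RPM). Their adjusted p was 7.28e-08 by camera, and adjusted p = 0.0903 with an estimated correlation. All 6 cell division genes rose, among them KNOLLE (4.18), with an adjusted p of 0.0228, and adjusted p = 0.251 with an estimated correlation. Phloem (2 of 3 fell, adjusted p = 0.00435), starch and sucrose (13 fell, 3 rose, adjusted p of 7.28e-08) and senescence (3 fell, 1 rose, adjusted p = 0.0121) were lower by camera, with adjusted p = 0.0337, 0.0637 and 0.218 with an estimated correlation. SUS4 rose from 48.2 ± 7.55 to 2840 ± 989 RPM. ASP4 (3.02) and ASP2 (2.45) were higher in C3 stem, also under RLE scaling (2.19 and 1.59), while NAD-ME1 was called with the deposited scaling (0.88) and not under RLE scaling (0.01). Of 26 C4 cycle enzymes 9 rose and 6 fell (9 and 5 adjusted over the list alone), or 7 and 10 under RLE scaling, and the list's median of 0.27 lies above 0 where camera, which compares with all other loci, is downward (adjusted p = 0.0186, and adjusted p = 0.378 with an estimated correlation). The transporters (7 rose, 1 fell, median 1.03) have a downward test (adjusted p = 0.992), and 4 rose and 4 fell under RLE scaling. Limma called 9354 of 12624 loci, 7965 higher and 1389 lower in stem. Under RLE scaling it called 7659, 4632 higher and 3027 lower, and 77 loci were called in opposite directions by the 2 scalings.

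Whether the species differ by organ was tested with the interaction, the C4 against C3 difference in leaf minus that in stem. The unknown sequencing mode of C3 stem limits this comparison too. DIC1, DIC2 and DIC3, higher in C4 leaf and lower in C4 stem, had interactions of 8.17 ± 0.54 (SE), 7.79 ± 0.53 and 7.39 ± 0.48 on the log2 scale, with limma adjusted p of 3.25e-09, 4.14e-09 and 2.60e-09. ASP2 (5.61), ASP4 (5.26), NAD-ME1 (3.86), ASP1 (3.82), PPDK (3.64), ALAAT1 (3.96, or 4.69 without C4 main-stem leaf replicate 1) and PPC1 (2.76) also differed more in leaf, while PLGG1 differed by -3.37. BCA1 (1.66, adjusted p = 0.0527) and NADP-ME2 (-0.69, adjusted p = 0.119) did not pass. BCA1 did without C3 branch leaf replicate 2 (1.80), C4 branch leaf replicate 3 (1.77) or C4 main-stem leaf replicate 1 (2.06), and without the last NADP-ME2 did as well (-0.80). Of 26 C4 cycle enzymes 11 rose and 2 fell in this sense, or 14 and 3 adjusted over the list alone, with an adjusted p of 2.24e-05, and adjusted p = 0.504 with an estimated correlation. Of 11 transporters 6 rose and 0 fell, or 6 and 1 adjusted over the list alone, with an adjusted p of 4.09e-05, and adjusted p = 0.504 with an estimated correlation. Of 21 secondary wall genes 19 rose and 0 fell, among them COMT1 (3.74) and CAD4 (2.33), with an adjusted p of 8.43e-13, and adjusted p = 0.171 with an estimated correlation. Photorespiration (1 rose, 9 fell, adjusted p = 0.0254) and the Calvin-Benson cycle (0 rose, 6 fell, adjusted p = 0.00318) went the other way, and so did chlorophyll synthesis (0 rose, 3 fell, adjusted p = 0.0269, and 0.0586 under RLE scaling), and adjusted p = 0.694 with an estimated correlation held for all 3. Limma called 2838 of 12624 loci, 1250 higher and 1588 lower, and 2859 under RLE scaling. Summing leaf libraries of 1 number raised the count to 4320.

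Genes higher in C4 leaf by at least 2-fold were compared with genes higher in C3 stem than in C3 leaf. Such genes include ASP2, ASP4, DIC1, DIC2 and DIC3, while PPDK and PPC1 were higher in C4 leaf and lower in C3 stem than in C3 leaf. Of 1272 genes 848 (66.7%) were also higher in C3 stem, where 783 would be from independent lists and 61.6% of all 11696 loci were. With no C3 leaf library shared, the overlap was 539 against 543 from independent lists with C4 leaf genes from branch leaves, and 579 against 537 with those from main-stem leaves. Under RLE scaling, with the C3 leaf libraries shared again, it was 565 against 424. The fold changes correlated across loci, which are not independent replicates, with r of 0.098 and a covariance of 0.174, against 0.413 and 0.032 in simulations of unchanged groups that share the C3 leaf libraries. The simulations hold noise only, so their r cannot be compared with the measured one. With no C3 leaf library shared, r was 0.026 (covariance 0.052) with C4 against C3 from branch leaves. It was 0.122 (covariance 0.215) with C4 against C3 from main-stem leaves.

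Root was compared between species only in the authors' deposited table, with no replicate values of C3 root used here. The sign of root in the authors' deposited table was taken to be that of leaf and stem, and if it is the other one, every direction in root turns. In the authors' deposited table PPC1 (log2 -0.14, q = 0.817), PPDK (-0.10, q = 0.869) and NAD-ME1 (0.39, q = 0.297) were not under a q of 0.05 in root, while ALAAT1 was lower in C4 root (-1.33, q = 0.0114). The authors' deposited table has DIC1 (-1.07), DIC2 (-1.43) and DIC3 (-2.23) lower in C4 root and also lower in C4 stem (-2.53, -3.04 and -3.91). Of 26 C4 cycle enzymes 6 were higher and 8 lower in C4 root at a q under 0.05 by the authors' deposited table. At that q the authors' deposited table counts 5426 loci in root, 7305 in stem, 6464 in branch leaves and 6883 in main-stem leaves.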

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

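The count of 2838 loci whose C4 against C3 difference is not the same in leaf and stem is listed because it is a difference between groups. Within the fixed gene lists, 9 genes were called in opposite directions in leaf and stem under both scalings of the RPM values. Whether DIC1, DIC2 and DIC3 among them are separate genes or reads of 1 gene spread over paralogs was not tested. The C4 against C3 difference in leaf minus that in stem was 8.17 for DIC1, 7.79 for DIC2 and 7.39 for DIC3 on the log2 scale, all mitochondrial dicarboxylate carriers that were higher in C4 leaf and lower in C4 stem. For the secondary wall and lignin genes COMT1, CAD5, CAD4 and XCP1 it was 3.74, 2.42, 2.33 and 1.99, and for the sucrose synthase SUS4 it was 2.91. P5CS1, of proline synthesis, went the other way at -2.13. CAD5 and P5CS1 were not called in leaf with main-stem leaves only (0.75, adjusted p = 0.0935, and -0.57, adjusted p = 0.145). SUS4 was not called in stem without C3 stem replicate 2 (-0.93, adjusted p = 0.0663). XCP1 was not called in leaf by edgeR (0.70, adjusted p = 0.0724), and not in stem without C3 stem replicates 2 and 3 (-1.08 and -0.91) or C4 stem replicates 1 and 2 (-1.16 and -0.98).

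Of 40 groups of values in which a library far from the others was looked for, 2 were marked, and chance alone marks about 5% of groups. In C4 main-stem leaf replicate 2 the mean log2 CPM of the leaf patterning regulators was 3.77, against a median of 3.18 in the other C4 leaf libraries. In C4 main-stem leaf replicate 1 the mean of the secondary wall and lignin list was 4.11, against a median of 5.09.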

How the results depend on the processing

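No named gene was called in the opposite direction under any setting. Among all loci 321 were called in the opposite direction in C4 stem against leaf with limma on RPM and 77 in C3 stem against leaf under RLE scaling. Under RLE scaling the split between the stems turned from 2369 higher and 1056 lower to 1444 and 1623, and the median of the C4 cycle list in C3 stem from 0.27 to -0.41. Of 171 named gene results compared over 3543 settings, 3396 comparisons kept their side of the threshold, 129 lost the call and 18 gained it. Those that gained it were ASP1 between the stems when only the groups compared were fitted, XCP1 in leaf in 3 settings, ASP1 and ALAAT1 in C3 stem against leaf in 3 each, and BCA1 and NADP-ME2 for the species difference in leaf minus stem in 6 and 2. Of the list members counted as called in leaf, MCM5, CCA1, LHCA1, GI, PSAE2 and CHLD lost the call in 10, 9, 9, 8, 3 and 2 of the 12 fits without 1 library. Between the leaves of the species 4320 loci were called, against 2803 at a 2-fold threshold, 2337 with branch leaves only and 2232 with main-stem leaves only, where the last 2 use fewer samples. For leaf position DESeq2 called 3 loci in C3 and 1 in C4 in place of 0, and the cause was not tested. Between the stems 3425 loci became 5177 when only the groups compared were fitted, and the 2838 loci of the leaf minus stem difference became 4320 when leaf libraries of the same number were summed, and the cause was not tested. The gene list tests passed in 56 cases, in 8 with an estimated correlation and in 53 under RLE scaling. The estimated correlation lay above the preset one in every fit for every list but phloem. For phloem it was 0.0507 in the leaf fit and -0.0212 in C4 root against leaf. The phloem adjusted p by camera rose in C4 root against leaf as well, from 0.00696 to 0.0751. What the fall from 56 cases to 8 comes from was not tested. The overlap of 66.7% of genes high in C4 leaf with genes high in C3 stem was 57.5% and 61.7% with no shared libraries. With shared libraries it was 44.4% under RLE scaling, where fewer stem genes are called (33.3% of loci against 61.6%). Leaving out 1 library at a time gave 3617 to 4609 loci in leaf, 0 for both leaf positions, 8569 to 9754 for C4 root, 7752 to 9210 for C4 stem, 2433 to 3173 between the stems, 8441 to 9278 for C3 stem and 2092 to 3353 for the leaf minus stem difference. With the replicate number as a block there were 3998 loci in leaf, 0 for both positions, 9189 in C4 root, 8555 in C4 stem, 3410 between the stems, 9321 in C3 stem and 2764 for the difference, and 55 list tests. With the block the senescence list in C3 leaf position (adjusted p = 0.0643) and, in leaf, PSAE2 (adjusted p = 0.052), LHCA1 (adjusted p = 0.0905) and CCA1 (adjusted p = 0.0531) lost their calls. The numbers were not taken to pair the samples, since the rule asked that every same-number pair correlate above 0.1, and only 6 of 45 same-number pairs on the counts and 10 of 63 on the RPM did. The 3 same-number pairs of C3 branch leaf with C4 main-stem leaf all correlated above 0.1, at 0.16 to 0.34 on the counts and 0.25 to 0.41 on the RPM. Settings added after seeing the data were halved leaf counts (4210 loci in leaf, 9641 in C4 root and 9069 in C4 stem), leaf libraries thinned to equal totals (2897 loci), libraries in doubt left out (4253 and 3597 loci in leaf) and limma on RPM in place of edgeR. Not run were the leaf minus root difference, C3 root against leaf, the overlap with root and all settings of the hybrids, whose samples are not used here, and DESeq2 and TMM on the RPM values, which are not counts. The simulations used the depth and number of these libraries, with the C4 stem depth in place of the unknown depth of C3 stem. Simulated 2-fold changes were found in 32% of loci in leaf, and in 3% and 6% for leaf position in C3 and C4. They were found in 29% in C4 root, 33% in C4 stem, 20% between the stems, 26% in C3 stem and 5% for the leaf minus stem difference. For 4-fold changes these were 77%, 48%, 55%, 82%, 77%, 76%, 78% and 57%.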

Other observations

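Loci called in opposite directions between the species in leaf and stem numbered 332 on the deposited RPM scale and 323 under RLE scaling, 225 of them in both. Of the 332, 145 were higher in C4 leaf and lower in C4 stem. Isocitrate lyase (ICL) stood at 445, 1348 and 1228 RPM in the C4 branch leaf libraries and at 7700, 388 and 161 in the C4 main-stem leaf libraries, against 62 to 74 in C4 stem and 0 to 3 in C3 leaf. ALAAT1 was at 641, 10510 and 17160 RPM in the C4 main-stem leaf libraries and at 14123, 7990 and 6397 in those of branch leaves.

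Chance as a cause of the counts was tested by dealing the same libraries into other groups. In leaf, C4 root, C4 stem and C3 stem only 1 of 100, 84, 84 and 84 splits, the real one, called as many loci (real 4229, 8276, 7446 and 8437, highest other 543, 0, 0 and 0). For the leaf minus stem difference it was 1 of 100 (real 2307, highest other 1413). These shares are under 0.05, so a random deal of these libraries rarely gave such counts. The labels do not name the plants, so chance among plants was not tested. For the stems the 10 splits are too few for a share under 0.05 (value 1, real 5177, highest other 0), as for leaf position in C3 (value 10, real 0, highest other 41) and in C4 (value 10, real 0, highest other 0).

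The tests in this paragraph were chosen only after the library had been seen: C4 main-stem leaf replicate 1 had a distance of 0.972 from the other C4 leaf libraries, below the 0.983 of main-stem replicate 3, and was the furthest only after thinning to equal totals. Its distance was then 1.24 times the largest of the others, and because it had no excess before thinning this does not test depth as a cause. Root tissue (median of root markers -1.02, genes from -3.1 to 0.95) and hour of harvest (0.07 between morning and later clock genes, the later ones from -1.02 to 1.59) stay open. The protocols give harvest at 2 h after the onset of light for every sample, and whether this library departed from it is not known. A low sugar state may be a biological cause, with a median of 1.04 over starvation genes not looked at before, 8 of 10 higher, but the exact sign test gave p = 0.109 and it stays open. The demand that a set also pass a sign test or lie close together was added after these values were seen. By the limits written before, the root marker and clock values would have counted against those causes. The starvation median would have counted for a low sugar state. With 5 root markers the sign test cannot give a p under 0.05, so it could not decide on root tissue. The root marker median was 1.95 in C4 main-stem leaf replicate 3, which is among the libraries compared against.

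A test chosen after the result was seen asked whether loci at least 8-fold different between the leaves could come from reads assigned to different Arabidopsis paralogs in the 2 species. Of 481 such loci 125 had a called best match, and 14.4% of these differed in the opposite direction (18 against 107 in the same direction, exact binomial p of 1.35e-16), against 18.5% among loci that differed by less than 8-fold. A switch of reads between a locus and its best match would give opposite directions. The values therefore argue against such a switch for the 107 loci with a match in the same direction. Reads of a gene spread over several paralogs would move these paralogs the same way. The test therefore cannot decide on such spreading, which stays open for all 481 loci. Loci and their matches are not independent, so the binomial p may overstate the evidence. A switch stays open for the 18 loci with an opposite match and for the 356 with no called best match. No biological explanation was tested.

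The tests in this paragraph were chosen after the result was seen and asked whether the C4 root and C4 stem counts of loci could come from counting both reads of a pair in leaf only, where low counts were mostly even. Such counting changes the ratio of 2 loci by at most 2-fold, and at least 4644 loci passed a test against a 2-fold change in either comparison, which argues against it as their cause. With leaf counts halved at least 9069 loci were called, but the scaling of libraries takes up most of such a factor, so this decides little. For loci within 2-fold the counting cannot be told from the biological difference between the organs. The share of even low counts separates all leaf libraries from all C4 stem and root libraries. Other effects of a difference in sequencing therefore cannot be told from organ at any fold change, and were not tested. C3 stem has no counts, so the comparisons with C3 stem could not be checked for this.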
